A study of Rattus norvegicus with 12 samples.

How the data were processed

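The 12 samples are arrays of total RNA from primary hepatocytes of Wistar rats, isolated with collagenase and purified on a Percoll gradient, per the labels and the series' design text. Total RNA was extracted with Trizol and cleaned on RNeasy columns, and biotinylated cRNA was prepared from 5 µg of it for Affymetrix arrays, per the labels' protocols. The deposited values are log2 values per probe set, made with RMA in the package affy under R 2.10.0, per the submitters' processing notes. RMA corrects the background, equalizes the distribution of probe intensities between arrays and summarises the probes of a set, so a shift shared by nearly all transcripts of a sample would not be visible in these values. The probe set definition file used is not given in the sources used here. Samples were assigned to 4 groups of 3 by the titles in the labels, which call them biological replicates, and replicate numbers were taken from there as well.

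The 57 control probe sets were left out, so that 31042 probe sets were tested. Gene names came from the platform annotation given with the data: 20832 probe sets had 1 gene symbol, 436 had several and 9780 were not listed, and a probe set of the last 2 kinds is not named here. Of the probe sets with 1 symbol, 20764 were matched by Entrez identifier to the RefSeq genes of assembly GRCr8, used for names alone, and 0 symbols changed. The 20826 tested probe sets with 1 symbol stand for 14217 genes. A gene is represented by its probe set with the highest mean over all 12 arrays, and 4525 genes had more than 1 probe set. No sequence or coordinate is used here.

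As quality measures, array medians ran from 5.16 to 5.21 log2, the 3' minus 5' difference of the actin control probe sets from 0.583 to 0.785 and of the GAPDH ones from 0.0570 to 0.133. Correlations between any pair of arrays over all probe sets ran from 0.979 to 0.997, and 0 pairs held identical values. The number of arrays, 3 per group, limits the precision.

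Differences between groups were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) in 1 fit over all 12 arrays with 4 groups and 8 residual degrees of freedom. The 4 comparisons were interferon alpha minus control at 3 h, the same at 6 h, the difference between these, and control at 6 h minus control at 3 h. P-values were adjusted by Benjamini-Hochberg over the 31042 probe sets within each comparison, and a probe set was called at an adjusted p under 0.05. All p-values from limma and camera are two-sided. Gene lists were tested with camera in limma on 1 probe set per gene, with a preset correlation between genes of 0.01, adjusted over the 30 lists within a comparison. The estimated correlation was run beside it: of the calls with the preset one, 5 of 8 held at 3 h, 7 of 9 at 6 h, 3 of 8 for the difference and 0 of 1 in untreated culture. Among lists that did not pass, the signs of median, mean and test differed at 3 h for JAK-STAT signalling, the NF-kB response, acute phase proteins, complement, cholesterol biosynthesis, cell cycle, Kupffer cells and neutrophils. They differed at 6 h for complement, cell cycle, Kupffer cells and erythroid cells, and for the difference between times for hepatocyte functions, dedifferentiation, Kupffer, stellate and cholangiocyte markers. In untreated culture they differed for chemokines, apoptosis, the NF-kB response, Kupffer cells and lymphocytes. Counts of list members are given over all probe sets and adjusted over the list alone. The lists hold antiviral effectors, nucleic acid sensors and adaptors, interferon receptor and JAK-STAT signalling, interferon regulatory factors, MHC class I and antigen processing, constitutive proteasome subunits, ISG15 conjugation, guanylate-binding proteins and immunity-related GTPases, chemokines and cytokines, apoptosis and cell death, and 20 further lists of hepatocyte functions, stress, growth and markers of other cell types. The groups, the tests, the lists and the rule for named genes were set before the data were examined.

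The rule for named genes took, for each treated comparison, the 12 genes with the largest rise on their brightest probe set and the 8 with the largest fall among those called with all 3 treated arrays on one side of all 3 controls, and for untreated culture the 5 in each direction. It further took from each list up to 4 members called in a treated comparison or, where 0 were called, the 2 brightest. Symbols starting with LOC or RGD were skipped. Genes outside the rule are said to have been chosen after their values were seen.

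Whether the replicate numbers pair the arrays was checked on the deviations of each array from its group mean. Arrays of the same number and time correlated at 0.651 to 0.829 over 6 pairs and arrays of the same number at different times at 0.479 to 0.736 over 12 pairs, while arrays of different numbers correlated at -0.562 to -0.0747. Deviations from a group mean cancel out within the group, so positive same-number correlations force negative ones on average between different numbers. The pairing thus comes from the data, through the same-number correlations, and what a number stands for is not given in the sources used here. The fit with the replicate number as a block over all 12 arrays, and a fit with a separate block within each time, were set as alternatives beforehand. Each separate block holds the arrays of 1 replicate number at 1 time, so that fit gives no value for control at 6 h minus control at 3 h. The blocks are fixed effects, and blocked values are given beside a result where they change it.

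The fits were tested on simulated values of the 31042 probe sets with 100 probe sets changed at each size. For the 3 h comparison the fit without a block recovered 84% of changes of 1 log2 and 94% of changes of 2, and for the 6 h comparison 82% and 95%, with 1 unchanged probe set called in each. With the block it recovered 98% and 100% at 3 h and 95% and 100% at 6 h, with 8 and 10 unchanged ones called. Each simulated change was the same in all 3 replicates. These shares therefore need not hold for responses that differ between replicates, as those at 3 h did. The camera step, run on 14115 genes, called the list that was shifted and 0 of the 29 others. The simulated genes varied independently of each other, so this run could not show false list calls caused by correlation between genes. In the data the estimated correlation ran from -0.0200 for nucleic acid sensors to 0.647 for constitutive proteasome subunits.

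Alternatives covered the block, quantile normalization, centring on array medians, cyclic loess, filters on dim probe sets (the 40% lowest means, or a mean under 5), 1 probe set per gene, limma-trend with robust spread, array weights, only the arrays of 1 time, stricter thresholds, the estimated correlation and the mean of all probe sets of a gene, and each array was left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Columns of values not used numbered 0.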

Results

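Gene expression was measured in primary hepatocytes of Wistar rats, which are liver cells taken from the animal and kept in short-term culture. On the day after isolation the cells were cultured with 250 U/ml rat interferon alpha, an antiviral cytokine, or without it, for 3 h or 6 h. The 12 Affymetrix arrays fall into 4 groups of 3 arrays, labelled as biological replicates 1 to 3 in each group. The deposited values are log2 RMA values per probe set, of which 31042 were tested, and array medians ran from 5.16 to 5.21. Below, a log2 change is given with the standard error of the limma fit (of the blocked fit for genes called with the block alone), and each group mean rests on 3 arrays, a number that limits the precision of every value.

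The comparison at 6 h asked which genes interferon alpha changed in hepatocytes after the longer exposure. Interferon alpha raised genes that block virus replication, each measured here on the brightest probe set of the gene. Cmpk2, a mitochondrial nucleotide kinase, rose by 4.90 ± 0.54 log2, 29.9-fold, from a mean level of 6.93 ± 0.52 (SD) in the control arrays to 11.83 ± 0.63 in the treated ones (adjusted p = 0.00325). Ifit3, which binds viral RNA in a complex with other Ifit proteins, rose 22.5-fold (4.49 ± 0.50 log2). Cxcl10, a chemokine that draws activated T cells, rose 20.5-fold (4.36 ± 0.52 log2), and Mx1, a dynamin-like GTPase active against influenza viruses, rose 20.1-fold (4.33 ± 0.51 log2). Ddx60, a helicase linked to viral RNA sensing, rose 19.2-fold with a wider error (4.26 ± 0.75 log2, adjusted p = 0.0404). The control means of Mx1 and Ddx60, 4.02 ± 0.37 and 4.18 ± 1.11 (SD), lay near the lower quartile of the arrays (3.84 to 3.93), where the share of background in the signal is not known and limits what both folds can show. Ifgga2l1, an interferon-inducible GTPase, rose 15.1-fold and Znfx1, a helicase that senses double-stranded RNA, rose 11.5-fold. The remaining genes among the 12 chosen for the largest rise of a brightest probe set were Ifit2 at 9.65-fold, the antiviral enzyme viperin (Rsad2) at 8.80-fold, the interferon-inducing transcription factor Irf7 at 8.62-fold, the ubiquitin ligase Rnf213 at 7.73-fold and the immunity-related GTPase Igtp at 7.43-fold. Adjusted p among these 12 genes ran from 0.00243 for Znfx1 to 0.0404 for Ddx60, and in each of them all 3 treated arrays lay above all 3 controls, as selection required.

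**Figure D1:**
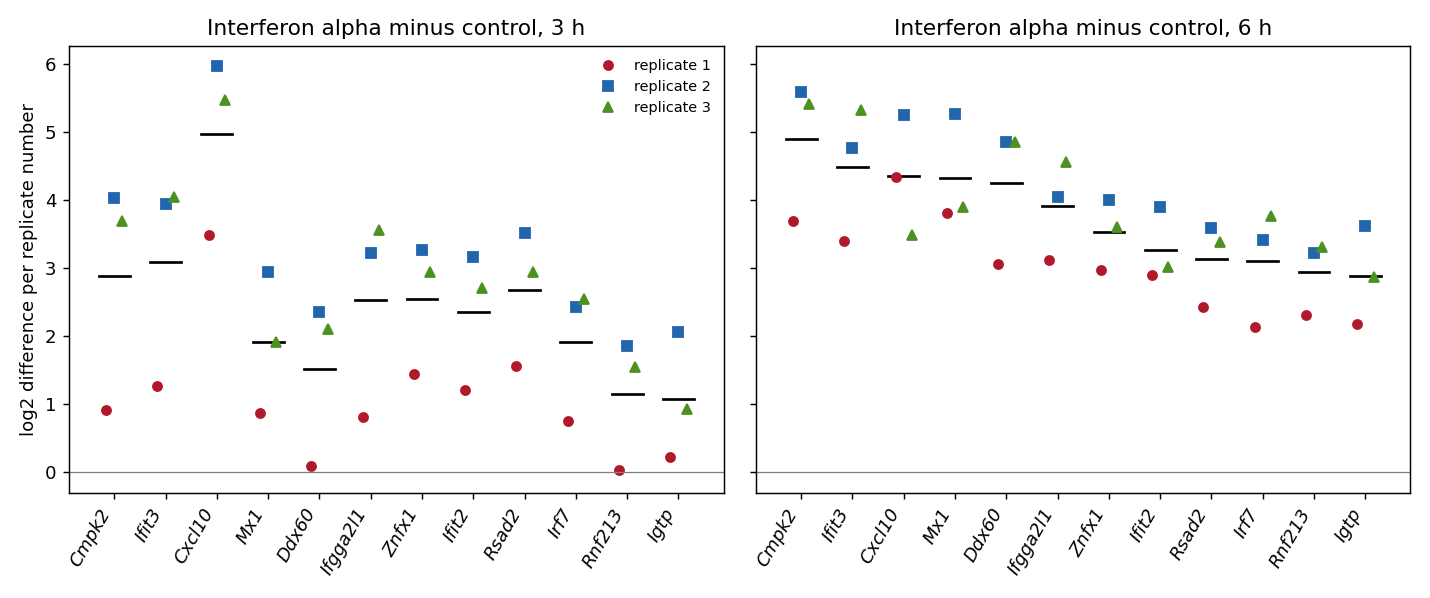
Log2 difference between the interferon alpha array and the control array of the same replicate number (vertical axis) for the 12 genes named for the largest rise at 6 h on their brightest probe set (horizontal axis), at 3 h on the left and 6 h on the right. Symbols stand for replicates 1 to 3 and each black bar for their mean; at 6 h every difference lies above 0, with Cmpk2 at a mean of 4.90, and at 3 h the replicate 1 difference is the smallest of the 3 in each gene.

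Over all 31042 probe sets tested, 120 rose at 6 h and 0 fell by limma, and 101 of the 120 rose at least 2-fold. At an unadjusted p under 0.05 by limma, 795 probe sets had higher and 350 lower values after treatment. Together these are fewer than the share of 0.05 of all probe sets that chance would let pass. In the blocked fits such probe sets exceeded that share, at 2539 with the block across times and 3670 with the block within each time. The 120 stood for 84 named genes and 20 probe sets that are not named here. With the replicate number as a block, 340 probe sets changed, 329 up and 11 down, and all 120 were among them, while without replicate 1, 2 or 3 in all groups the blocked fit called 291, 127 and 100. Of the 11 that fell, the named ones were Etfbkmt at -0.71 log2 (blocked adjusted p = 0.00154), Crybg2 at -0.50 (0.0150), Klf15 at -0.52 (0.0343) and Lmbr1l at -0.47 (0.0176), chosen after their values were seen. Klf15, a glucocorticoid-responsive transcription factor, had a brighter probe set at -0.38 that did not pass (0.131), and Etfbkmt and Lmbr1l were likewise called through a probe set that is not their brightest. Without the interferon alpha 6 h array of replicate 2, 56 probe sets rose, and without the control 6 h array of replicate 2 or of replicate 3 the count was 73 or 71. With only the 6 h arrays in the fit it was 69, and Cxcl11, Ddx60, Dhx58, Irf9, Nlrc5, Stat2, Uba7 and Usp18 missed the threshold (adjusted p from 0.0508 to 0.188). Limma-trend also ended the call of Ddx60 (0.0801). Some genes named for this comparison missed the threshold with 1 array left out. Ddx60 did so without any 1 of 8 arrays, namely all except the control 3 h arrays of replicates 1 and 3, the interferon alpha 3 h array of replicate 2 and the control 6 h array of replicate 1 (adjusted p from 0.0510 to 0.230). Without the interferon alpha 6 h array of replicate 2 alone it happened to Ifgga2l1 (0.0539), Igtp (0.0539) and Uba7 (0.0566). Without that array or another 6 h array it happened to Cxcl11 (control of replicates 2 and 3, treated of replicate 1, 0.0631 to 0.105), Usp18 (control 2 and 3, treated 3, 0.0831 to 0.113), RT1-N3 (control 1, 2 and 3, treated 3, 0.0649 to 0.112), Dhx58 (control 2 and 3, treated 3, 0.0685 to 0.116), Irf9 (control 2, treated 1 and 3, 0.0642 to 0.103) and Stat2 (control 2, treated 3, 0.0522 to 0.0713).

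Antiviral effectors, the list fixed before the data were examined that held more called genes than any other, rose at 6 h. Of 50 measured antiviral effectors, 26 rose and 24 did not pass, 37 rose adjusted over the list alone, and the median change was 1.86 log2 (camera adjusted p = 1.17e-96, 0.00197 with an estimated correlation). The lists whose 6 h call held with an estimated correlation had camera adjusted p there from 0.00197 to 0.00745, the latter for interferon regulatory factors. With the replicate block 37 of the 50 rose. Of 14 nucleic acid sensors and adaptors, 3 rose and 11 did not pass, with 7 adjusted over the list alone (camera adjusted p = 7.36e-11). The 3 were the cytosolic RNA sensors Ifih1 (MDA5) at 2.14 ± 0.25 log2, Rig1 (the symbol given for RIG-I) at 1.77 ± 0.20 and Dhx58 (LGP2) at 1.47 ± 0.23. Of 7 interferon regulatory factors, Irf7 (3.11 ± 0.36 log2) and Irf9 (1.20 ± 0.19) rose, 3 passed adjusted over the list alone, and the list had an adjusted p of 4.85e-08. Irf1, chosen after its values were seen, was 2.22 ± 0.29 log2 higher with an adjusted p of 0.0608, and 0.00203 with the block. The interferon receptor and JAK-STAT list of 23 genes passed camera (adjusted p = 0.00503, 0.0813 with an estimated correlation) on 3 members, both over all probe sets and adjusted over the list alone, and its median change was 0.01 log2. These 3 were Usp18, which dampens interferon receptor signalling, at 2.21 ± 0.35 log2, and Stat2 at 1.51 ± 0.21 and Irf9, components of the transcription factor that interferon alpha activates. Another probe set of Stat2, at 1.55 log2, did not pass without the block (adjusted p = 0.0849, 0.000456 with it). Without the control 6 h array of replicate 2 or the interferon alpha 6 h array of replicate 1, this list had an adjusted p of 0.262 or 0.0565.

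Antigen presentation genes rose with a smaller median than the antiviral effectors. Of 23 genes of MHC class I and antigen processing, 3 rose, 7 adjusted over the list alone and 11 with the replicate block, with a median of 0.44 log2 (camera adjusted p = 6.08e-17). Tap1, a subunit of the peptide transporter into the endoplasmic reticulum, rose by 2.35 ± 0.27 log2 on its brightest probe set, while another Tap1 probe set at 0.40 did not pass. Nlrc5, the transactivator of MHC class I genes, rose by 1.99 ± 0.26, and RT1-N3, a class Ib MHC gene, by 1.87 ± 0.29. The immunoproteasome subunits Psmb9 and Psmb8, chosen after their values were seen, were 1.33 and 0.74 log2 higher, with adjusted p of 0.108 and 0.326, and 0.00178 and 0.00223 with the block. The 30 constitutive proteasome subunits had a median of -0.04 and no call (camera adjusted p = 0.745), with Psma6 at 0.04 ± 0.10 and Psmb5 at -0.02 ± 0.13. Without the control 6 h array of replicate 3 that list was lower, with an adjusted p of 0.00386.

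The pathway that attaches Isg15, a ubiquitin-like protein, to other proteins rose at several steps. Of its 7 measured genes 4 rose, 6 adjusted over the list alone and all 7 with the block (median 1.66 log2, camera adjusted p = 4.03e-24). Isg15 itself rose by 2.68 ± 0.33 log2, its ligase Herc6 by 2.05 ± 0.26, its activating enzyme Uba7 by 1.66 ± 0.23, and Usp18, which removes Isg15, by 2.21 ± 0.35. The largest list median belonged to the guanylate-binding proteins and immunity-related GTPases, which act on membranes around intracellular pathogens, at 2.85 log2 over 7 genes (camera adjusted p = 3.67e-17). Here Igtp (2.89 ± 0.39 log2), Irgm (2.85 ± 0.26) and Irgm2 (2.55 ± 0.26) rose, 5 passed adjusted over the list alone, and 6 with the block. Of 33 chemokines and cytokines, Cxcl10 and the related T cell chemokine Cxcl11 (2.70 ± 0.41 log2) rose, 5 passed adjusted over the list alone and 6 with the block (camera adjusted p = 0.000346, 0.253 with an estimated correlation). That list had an adjusted p of 0.0933 without the control 6 h array of replicate 2 and 0.129 without the interferon alpha 6 h array of replicate 1. Of 30 apoptosis and cell death genes, Pml, the scaffold of nuclear bodies, rose by 2.18 ± 0.25 log2 and 29 did not pass, with 4 adjusted over the list alone and 6 with the block (camera adjusted p = 4.15e-08). Tnfsf10, the death ligand TRAIL and a member of both lists, with a control mean of 3.31 ± 0.19 (SD), below the lower quartile of the arrays, was 3.02 ± 0.37 log2 higher (adjusted p = 0.0514, 0.00132 with the block), and was chosen after its values were seen.

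Hepatocyte functions gave no list call at 6 h. The adjusted p was 0.745 for hepatocyte transcription factors and differentiated functions, 0.677 for cytochromes P450 and drug metabolism, 0.905 for acute phase proteins and 0.386 for complement. It was 0.655 for cholesterol biosynthesis, 0.227 for fatty acid oxidation and PPAR alpha targets, and 0.0732 for one-carbon and methionine metabolism, which passed with the replicate block (0.0296, 0.503 with an estimated correlation besides) at a median of -0.05 log2. Albumin (Alb) was at 0.02 ± 0.06 log2, the ethanol-metabolizing Cyp2e1 at -0.01 ± 0.07 and complement C3 at 0.00 ± 0.11. Alb was the brightest gene of its lists, and whether so bright a probe set could show a change was not tested. For stress and growth the adjusted p was 0.418 for the NF-kB response, 0.294 for immediate early genes, 0.677 for cell cycle and DNA replication, 0.905 for the unfolded protein and amino acid stress response, 0.905 for heat shock proteins and 0.835 for dedifferentiation and cytoskeleton. Markers of other cells gave 0.905 for Kupffer cells and macrophages, 0.745 for liver endothelial cells, 0.591 for stellate cells and fibroblasts, 0.386 for cholangiocytes, 0.619 for lymphocytes and NK cells, 0.393 for neutrophils and 0.966 for erythroid cells. Among the brightest of these markers, the monocyte receptor Cd14 was at 0.01 ± 0.17 log2 and the cholangiocyte marker Epcam at 0.08 ± 0.29. With the block within each time, fatty acid oxidation (0.0432) and immediate early genes (0.0432) passed. Without the control 6 h array of replicate 3, fatty acid oxidation (0.00316), one-carbon metabolism (0.0192) and cytochromes P450 (0.0474) passed, and without that of replicate 1, complement (0.00692), the NF-kB response (0.0198) and immediate early genes (0.0236). Complement also passed without the interferon alpha 6 h array of replicate 3 (0.000272), and one-carbon metabolism without that of replicate 1 (0.0215).

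At 3 h, the shorter exposure, Cxcl10 had already risen 31.6-fold (4.98 ± 0.52 log2, adjusted p = 0.0372 by limma). Its differences in replicates 1 to 3 were 3.49, 5.97 and 5.47 log2. The other called probe set, unnamed in the annotation and singled out after its values were seen, rose by 0.66 log2 (adjusted p = 0.0486). In all, 2 probe sets rose and 0 fell by limma, while 646 were higher and 269 lower at an unadjusted p under 0.05. Together the latter are fewer than the share of 0.05 of all probe sets that chance would let pass. In the blocked fits they exceeded it, at 2094 with the block across times and 3122 with the block within each time. With the replicate number as a block, 29 probe sets rose and 1 fell. That blocked fit called 112 probe sets without replicate 1 in all groups and 0 without replicate 2 or without replicate 3, with 1575 and 1353 at an unadjusted p under 0.05, and a block within each time called 10. Among the genes named for the 6 h response, the block called Ifit3 at 3.09 ± 0.48 log2 (blocked adjusted p = 0.0499), Rsad2 at 2.68 ± 0.33 (0.0184), Znfx1 at 2.55 ± 0.29 (0.0147) and Ifit2 at 2.36 ± 0.31 (0.0218). Without the block their adjusted p were 0.154, 0.0720, 0.0720 and 0.0933. Also called with the block, and chosen after their values were seen, were Ncoa7, a nuclear receptor coactivator, at 3.35 ± 0.40 log2 (0.0174, 0.0720 without it) and Irf1 at 2.24 ± 0.29 (0.0218, 0.322 without it). The probe set that fell with the block was that of Phrf1, a ring finger protein, at -0.63 log2 (0.0499, 0.154 without it).

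The 3 h calls depended on single arrays. Without the interferon alpha 3 h array of replicate 1, 23 probe sets rose, Znfx1 (adjusted p = 0.000326), Ifit2 (0.00144), Rsad2 (0.00252), Ifit3 (0.00852), Irgm (0.0209), Pml (0.0209) and Cmpk2 (0.0299) among them, whereas Cxcl10 missed the threshold without any 1 of the control 3 h arrays, the interferon alpha 3 h arrays of replicates 2 and 3, the control 6 h arrays of replicates 2 and 3, and the interferon alpha 6 h arrays of replicates 1 and 2 (0.0604 to 0.272), and the count was then 0. Without the interferon alpha 6 h array of replicate 3 it was 1, and without the control 6 h array of replicate 1 it was 3, Rsad2 included (0.0497). Cxcl10 also missed the threshold with only the 3 h arrays in the fit (0.914) and with limma-trend (0.0763).

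The gene lists moved at 3 h although few single genes passed. Antiviral effectors had a median of 0.76 log2 over 50 genes, 0 of which passed over all probe sets, 25 adjusted over the list alone and 7 with the block (camera adjusted p = 3.53e-46, 0.0300 with an estimated correlation). The lists whose 3 h call held with an estimated correlation had camera adjusted p there from 0.0300 to 0.0330, the latter for nucleic acid sensors. Cmpk2 was 2.88 ± 0.54 log2 higher (adjusted p = 0.324) and Mx1 1.91 ± 0.51 (1.00). ISG15 conjugation had a median of 0.89 log2 with 5 of 7 genes adjusted over the list alone (adjusted p = 6.36e-14), and the guanylate-binding proteins and immunity-related GTPases 1.21 log2 with 3 of 7 (adjusted p = 8.89e-07). Interferon regulatory factors (3 of 7 adjusted over the list alone, adjusted p = 2.33e-06) and nucleic acid sensors (2 of 14, 0.00170) passed as well. Chemokines and cytokines passed with 2 of 33 genes adjusted over the list alone, Cxcl10 being the one called over all probe sets (adjusted p = 5.73e-05, 0.217 with an estimated correlation). MHC class I genes passed with 1 of 23 (adjusted p = 5.73e-05, 0.202 with an estimated correlation). Apoptosis genes had 0 of 30 (adjusted p = 0.0346, 0.217 with an estimated correlation), a call that ended without the control 3 h arrays of replicate 2 (0.0633) or 3 (0.259) or the interferon alpha 3 h array of replicate 2 (0.215). The JAK-STAT list did not pass (0.566), and immediate early genes, which respond to growth factors and stress within minutes, had an adjusted p of 0.233 that the block moved to 0.0117 (0.509 with an estimated correlation besides) at a median of -0.12 log2. Without the control 3 h array of replicate 1, the markers of Kupffer cells and macrophages (0.0257), liver endothelial cells (0.00359), stellate cells (0.0365) and lymphocytes (0.0424) passed, and their adjusted p with all arrays were 0.998, 0.616, 0.497 and 0.149. Without the interferon alpha 3 h array of replicate 3, complement (0.0387), the unfolded protein response (0.0220), immediate early genes (0.0301) and erythroid markers (0.0136) passed, immediate early genes also without the control 3 h array of replicate 2 (6.50e-05), and constitutive proteasome subunits without that of replicate 3 (0.00941). With the replicate block and an estimated correlation together, no list passed at 3 h, the lowest adjusted p being 0.0729, that of antiviral effectors among them. With all arrays the lists that did not pass at 3 h had adjusted p from 0.134 for erythroid markers to 0.998.

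**Figure D2:**
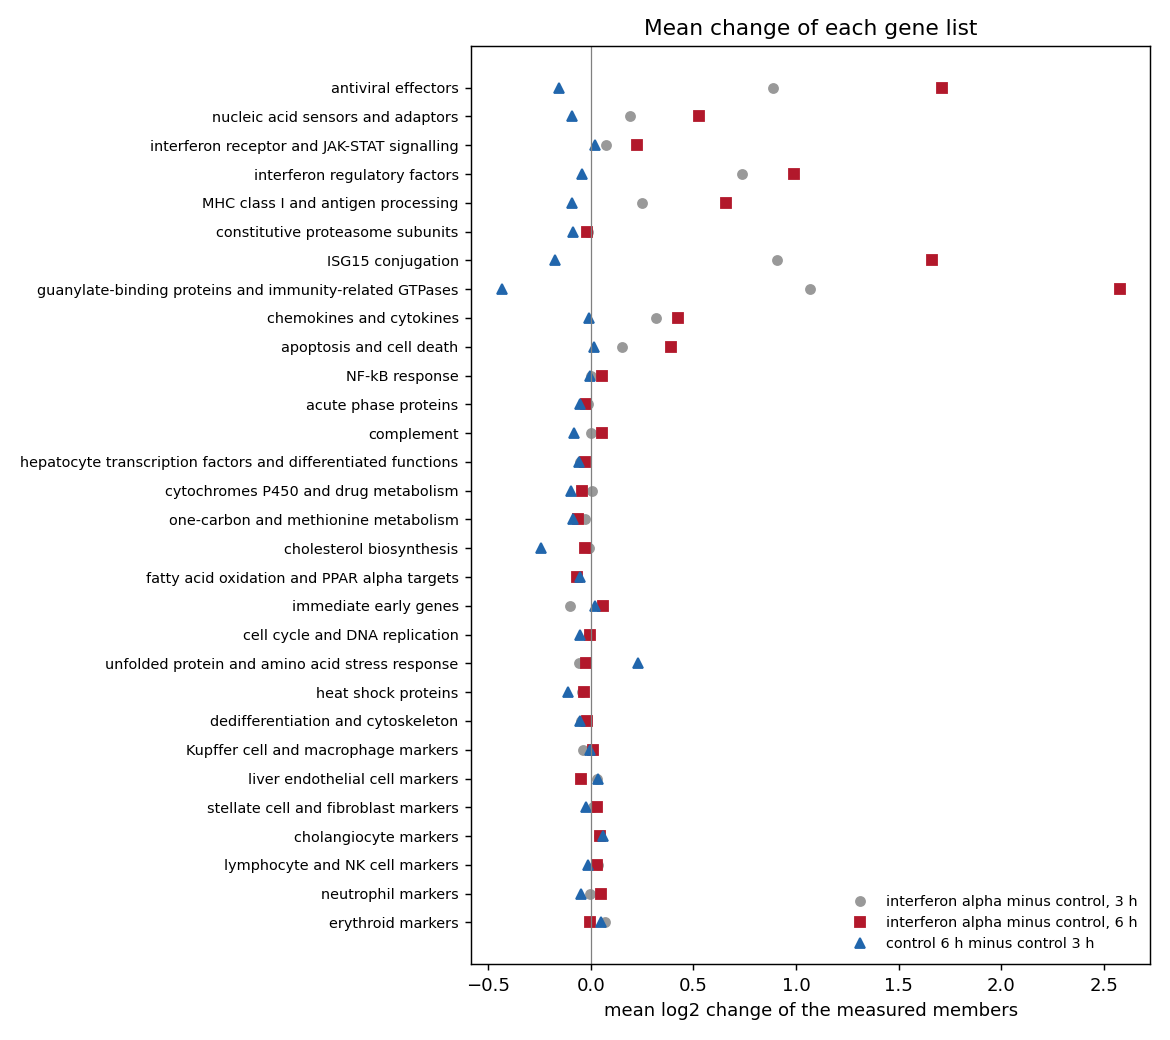
Mean log2 change over the measured members of each of 30 gene lists (vertical axis, 1 line per list) for interferon alpha minus control at 3 h and at 6 h and for control at 6 h minus control at 3 h (horizontal axis, log2). Symbols mark the 3 comparisons. The guanylate-binding proteins and immunity-related GTPases lie at 1.07 at 3 h and 2.58 at 6 h, antiviral effectors at 0.89 and 1.71, and the hepatocyte lists near 0 for both interferon alpha comparisons. For control at 6 h minus control at 3 h, cholesterol biosynthesis lies at -0.24.

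The design also allows a test of whether the response differed between 3 h and 6 h. The guanylate-binding proteins and immunity-related GTPases showed the largest list difference, a mean of 1.51 log2 more at 6 h (camera adjusted p = 6.36e-09), with 3 of 7 genes adjusted over the list alone. Antiviral effectors gained 0.82 log2 (1.30e-34), with 10 of 50 adjusted over the list alone, and nucleic acid sensors 0.34 (9.99e-06), with 2 of 14. With an estimated correlation the camera adjusted p was 0.0420 for antiviral effectors, 0.0251 for nucleic acid sensors and 0.0251 for the guanylate-binding protein list. ISG15 conjugation gained 0.76 (adjusted p = 1.92e-07, 0.0734 with an estimated correlation), MHC class I genes 0.41 (adjusted p = 2.10e-07, 0.0742 with an estimated correlation) and apoptosis genes 0.24 (adjusted p = 0.00103, 0.0734 with an estimated correlation). The JAK-STAT list gained 0.15 (adjusted p = 0.0366, 0.211 with an estimated correlation and 0.0886 with the replicate block). Immediate early genes gained 0.16 (adjusted p = 0.0366, 0.710 with an estimated correlation), from -0.10 at 3 h to 0.06 at 6 h. The call on the JAK-STAT list ended without any 1 of 8 arrays (0.0645 to 0.461) and that on immediate early genes without any 1 of 6 (0.0682 to 0.648). With the replicate block and an estimated correlation together no list passed, the lowest adjusted p being 0.104 for nucleic acid sensors. Without the control 6 h array of replicate 1, interferon regulatory factors (0.00623, 0.211 with all arrays) and complement (0.0248) passed as well. Without that of replicate 3, constitutive proteasome subunits (0.0142) and cytochromes P450 (0.0271) did, cytochromes P450 also with the block within each time (0.0391). Complement passed without the interferon alpha 6 h array of replicate 3 (0.00213), and the proteasome list (0.00672) and erythroid markers (0.0477) without the interferon alpha 3 h array of replicate 3. Kupffer cell markers passed without that of replicate 1 (0.0336) and liver endothelial markers without the control 3 h array of replicate 1 (0.00295). Chemokines and cytokines did not pass (0.958), and Cxcl10 stood at 4.98 log2 at 3 h and 4.36 at 6 h. No single probe set passed with all arrays: limma called 0, with 673 at an unadjusted p under 0.05, and the fit with the replicate block also called 0, with 1466. Each of these unadjusted counts is under the share of 0.05 of all probe sets that chance would let pass. The block within each time also called 0, but with 2094 at an unadjusted p under 0.05, which is over that share. Without replicate 1 in all groups, however, the fit with the block across times called 18 probe sets, all with a higher response at 6 h (smallest adjusted p = 0.0193). Without replicate 2 or 3 that fit called 0, with 1239 and 1258 at an unadjusted p under 0.05.

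Genes called at 6 h were mostly higher at 3 h as well. Of the 120 probe sets called at 6 h, 119 had a higher treated mean at 3 h, and in 93 all 3 treated arrays lay above all 3 controls, where chance gives 5%. With arrays paired by replicate number, 107 of the 120 were higher in all 3 pairs at 3 h, where chance gives 12.5%. Both chance shares hold for 1 probe set alone, and the 120 were measured on the same arrays and are not independent. Their calls also used the spread of all 12 arrays, those at 3 h included. Their median change was 0.83 log2 at 3 h and 1.99 at 6 h, and 118 of them were larger at 6 h. They were chosen for their 6 h values, which favours a larger change at 6 h. The limma test of the difference itself called 0 probe sets. By replicate number, the median difference of the 120 at 3 h was 0.26, 1.24 and 1.08 log2 for replicates 1, 2 and 3, and at 6 h it was 1.42, 2.30 and 2.11. Of the 329 probe sets that rose at 6 h with the replicate block, 315 had a higher treated mean at 3 h. In 133 of the 329 all 3 treated arrays lay above all 3 controls at 3 h, and 245 were higher in all 3 pairs. The median change of the 329 was 0.40 log2 at 3 h and 0.99 at 6 h. The 3 h and 6 h effects share no arrays, and across 14217 genes they correlated with Pearson's r of 0.677 and Spearman's rho of 0.305. Across the 80 genes whose brightest probe set was called at either time, Irf7 and Isg15 included, r was 0.858 and rho 0.911. These correlations are across genes, which are not independent replicates. Both times called 1 probe set in common, that of Cxcl10, where independent lists would share 0.00773, and with the block they shared 24 risen probe sets, where 0.307 would be shared.

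The untreated arrays were also compared between 6 h and 3 h of culture, without interferon alpha. Whether the further culture itself caused the differences was not tested. The 5 genes named in each direction were chosen on the brightest probe set of each gene. Spice1, a centriole protein, rose by 1.04 ± 0.17 log2 (adjusted p = 0.0493), the autophagy-related coactivator Calcoco1 by 0.99 ± 0.13 (0.0275), the ring finger gene Rnf39 by 0.95 ± 0.11 (0.0250), the secretory pathway cargo protein Tmed5 by 0.92 ± 0.13 (0.0365), and the BMP receptor Bmpr2 by 0.75 ± 0.11 (0.0365). A second Bmpr2 probe set was at -0.01 and did not pass. Smpd3, a neutral sphingomyelinase, was at -1.05 ± 0.18 log2 (0.0493), Paqr9, a receptor family protein, at -0.97 ± 0.15 (0.0365), Mtap, which salvages methionine, at -0.89 ± 0.12 (0.0296), Disp1, which releases Hedgehog proteins, at -0.83 ± 0.12 (0.0365), and Prkar1b, a regulatory subunit of protein kinase A, at -0.83 ± 0.12 (0.0365). These 5 fell. In total 28 probe sets rose and 31 fell between 3 h and 6 h, and all 59 had the same sign in the interferon alpha arrays. With the replicate block, 1033 rose and 1496 fell, and 97.7% of these 2529 had the same sign in the interferon alpha arrays. How often signs would match without a change is not known, since untreated and treated arrays of the same number and time deviate together (r from 0.651 to 0.829). The blocked fit called 660 without replicate 1 in all groups (201 up, 459 down), 581 without replicate 2 (314 up, 267 down) and 497 without replicate 3 (195 up, 302 down). Leaving out any 1 of the 12 arrays brought the count to between 2 and 16. Smpd3 and Spice1 missed the threshold without any 1 of the 12, and all 10 named genes did without any 1 of the control 3 h arrays, the control 6 h arrays of replicates 1 and 3 or the interferon alpha 3 h array of replicate 2 (0.0504 to 0.173). Smpd3 and Spice1 also missed it with median centring (0.0543 each) and with 1 probe set per gene (0.0552 and 0.0518), with Bmpr2, Disp1, Paqr9, Prkar1b and Tmed5 beside them with limma-trend (0.0588 to 0.0752), and Bmpr2 (0.130), Mtap (0.0914) and Smpd3 (0.0562) with the mean of all probe sets of a gene. Cyclic loess (0.0551) and array weights (0.0513) ended the call of Smpd3 as well. One probe set per gene gave 22 calls, limma-trend 14, a 2-fold minimum 8 and an adjusted p under 0.01 2.

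**Figure D3:**
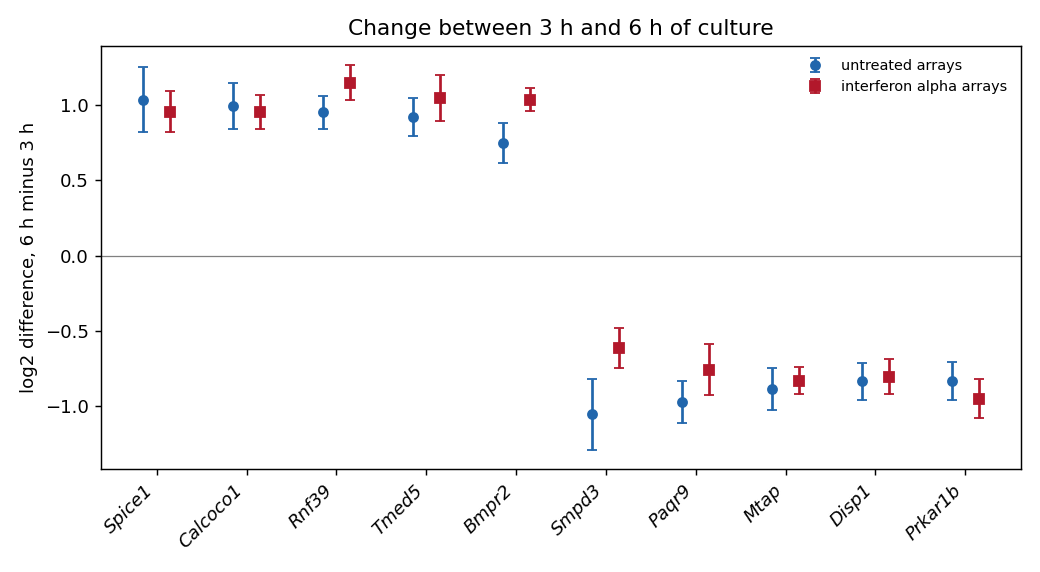
Log2 difference between 6 h and 3 h of culture (vertical axis) for the 10 genes named for untreated culture (horizontal axis), in untreated and in interferon alpha arrays. Points are differences of group means of 3 arrays and bars their standard errors; the 5 genes at the left lie above 0 and the 5 at the right below 0 in both, as with Spice1 at 1.04 and Smpd3 at -1.05 in the untreated arrays.

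By list, cholesterol biosynthesis fell in untreated culture, with a median of -0.22 log2 over 23 genes (camera adjusted p = 0.00120, 0.674 with an estimated correlation). Of these, 1 fell over all probe sets, 5 fell and 1 rose adjusted over the list alone, and 9 fell and 1 rose with the replicate block. Mvd, mevalonate diphosphate decarboxylase, fell by 0.80 log2 with an SE of 0.10 (adjusted p = 0.0275). Msmo1, a sterol oxidase, was at -0.76 ± 0.10 log2 (adjusted p = 0.132, 0.00259 with the block), Idi1, an isomerase of the same pathway, at -0.68 ± 0.11 (0.194, 0.00522) and Hsd17b7, a sterol ketoreductase, at -0.62 ± 0.09 (0.368, 0.00391). Insig2, which holds the sterol sensor in the endoplasmic reticulum, was 0.81 ± 0.15 log2 higher (0.215, 0.00922). The list call ended without the control 6 h array of replicate 3 (0.0608). The unfolded protein and amino acid stress response had an adjusted p of 0.0563, and 0.00171 with the block (0.891 with an estimated correlation besides), at a median of 0.14 log2. With the block 7 of its 22 genes rose and 2 fell, among them the stress transcription factor Ddit3 (CHOP) at 0.88 ± 0.10 log2 (0.000963), the glutathione-degrading enzyme Chac1 at 1.07 ± 0.22 (0.0139) and the translation-restoring phosphatase subunit Ppp1r15a at 0.70 ± 0.11 (0.00405), whose adjusted p without it were 0.443, 0.176 and 0.471. The chaperones Hspa5 at 0.05 ± 0.15 and Hsp90b1 at 0.00 ± 0.18 did not pass in either fit. Apart from Insig2, Hspa5 and Hsp90b1, the members named here were chosen after their values were seen. Albumin (Alb) was at -0.05 ± 0.06 log2, on a probe set so bright that whether it could show a change was not tested. The antiviral effectors, with interferon alpha absent, were at a median of -0.13 (camera adjusted p = 0.235), and this list passed without the control 6 h array of replicate 1 (0.00133) or the control 3 h array of replicate 3 (0.0299). Guanylate-binding proteins and immunity-related GTPases (0.0272) and constitutive proteasome subunits (0.0272) also passed without the former array, and the proteasome list without the latter (0.00271). The unfolded protein list passed without any 1 of the control 3 h and interferon alpha 3 h arrays of replicate 3 and the control 6 h and interferon alpha 6 h arrays of replicate 2 (0.000767 to 0.0478), and with the dimmest genes left out (0.0327). The fatty acid oxidation list, at 0.0923, passed without the control 6 h array of replicate 1 (0.0272) or 2 (0.0283), and the other lists had adjusted p up to 0.991.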

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

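The tests of replicate 1 at 3 h and their additional checks were chosen after its values were seen, while the tests of the list differences and the counts over other splits were set beforehand.

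A difference between the responses at 3 h and 6 h, by the camera test of the difference itself, was found for 8 lists. The mean log2 difference, 6 h minus 3 h, was 1.506 for guanylate-binding proteins and immunity-related GTPases, 0.8206 for antiviral effectors, 0.7554 for ISG15 conjugation, 0.4077 for MHC class I and antigen processing, 0.3375 for nucleic acid sensors and adaptors and 0.2374 for apoptosis and cell death. It was 0.1533 for interferon receptor and JAK-STAT signalling, whose call the block ended (adjusted p = 0.0886), and 0.1602 for immediate early genes. With an estimated correlation 5 of the 8 calls ended, those on ISG15 conjugation (adjusted p = 0.0734), MHC class I (0.0742), apoptosis (0.0734), JAK-STAT signalling (0.211) and immediate early genes (0.710), and with the block besides, the other 3 ended too (0.104 to 0.187). Cldn7, a tight junction gene, differed by -0.1868 because its change was above 0 in all 3 pairs at 3 h and below 0 in all 3 at 6 h, a rule on signs in which the difference was not tested (limma's test of it, run for all probe sets, gave an adjusted p of 1.00). Its differences by replicate were 0.37, 0.01 and 0.11 log2 at 3 h and -0.02, -0.02 and -0.04 at 6 h, with a control SD of 1.06 at 3 h.

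Replicate 1 responded weakly at 3 h, where over the 120 probe sets called at 6 h its difference fell short of that in replicates 2 and 3 by a median of 0.92 log2 (89.2% of them were higher in its treated array), and at 6 h, where its median difference was 1.42 log2 against 2.30 and 2.11, a gap that causes peculiar to the 3 h arrays would leave unexplained. At 3 h, higher basal expression in its control does not account for the whole shortfall, since the median excess of that control was 0.32 log2, a ratio of 0.3502 to the shortfall (95% bootstrap interval over probe sets 0.241 to 0.435), and the treated array itself was lower by 0.52. The intervals in this paragraph resample probe sets and not arrays, so they leave out the spread between arrays. The replicate 1 values at 3 h rest on 1 control and 1 treated array. A slower response and treated RNA mixed with untreated RNA or unresponsive cells cannot be told apart: across 102 probe sets that rose by at least 0.5 log2 in replicates 2 and 3, a minimum set afterwards, the fraction of the rise kept (median 0.142) correlated with earliness (the rise at 3 h over that at 6 h in replicates 2 and 3) at a Spearman rho of 0.4481 (0.241 to 0.610), which a later response would give. With the replicate 1 control replaced by the mean of the other controls, however, rho was -0.179 (-0.371 to 0.0305), so the sign changes with the control used, while a control level of at least 5 left 0.426 and holding control level and size at 6 h fixed left 0.420. The 3 h rise in replicates 2 and 3 divides the fraction kept and multiplies earliness, so its noise alone would push rho below 0. The other controls are part of that rise, so the replacement adds a further shared term. A biological difference between the samples behind the replicate numbers was not tested and stays open.

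Only 10 splits of the 6 arrays of a comparison exist, too few for a share under 0.05. Every other split mixes the groups being compared, so a real difference between them widens the spread and lowers the count. Low counts in the other splits therefore decide nothing. The real split called 2 probe sets at 3 h and 120 at 6 h, and the highest of the other splits called 0 in both, with 1 split of 10 reaching the real count. In untreated culture the real split called 59 and the highest other 0, again 1 split of 10. For the difference between times the real split called 0 as did the highest other, so that 10 of 10 splits reach it, as any count would. Of the 10 splits, 4 part as many of the numbered pairs as the real one, the real one included, and the highest of the others called 0, as did the highest of those that part 1 pair.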

How the results depend on the processing

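Cyclic loess, the list tests with the block across times, alone or with an estimated correlation, and the blocked fits without 1 replicate number were chosen after seeing the data, and the other alternatives were set beforehand. At 3 h, where 2 probe sets were called, the replicate block across times gave 30 and the block within each time 10. There, median centring, cyclic loess, leaving out the 40% dimmest probe sets, a mean of at least 5, 1 probe set per gene and a 2-fold minimum each gave 1, and limma-trend, an adjusted p under 0.01 and the 3 h arrays alone gave 0, with 914, 915 and 752 at an unadjusted p under 0.05. Chance would let pass a share of 0.05 of all probe sets, which is more than each of these unadjusted counts. The block across times and the block within each time had 2094 and 3122 there, each more than that share. Single arrays left out gave 0 to 23 calls. At 6 h, against 120, the block gave 340 across and 341 within times, an adjusted p under 0.01 and the 6 h arrays alone 69 each, and single arrays left out 56 to 124. In untreated culture, against 59, the block across times gave 2529, 1 probe set per gene 22, limma-trend 14, a 2-fold minimum 8, an adjusted p under 0.01 2, and single arrays left out 2 to 16. The block within each time gives no value there, since each of its blocks lies within 1 time. Scaling moved its split of 28 risen and 31 fallen to 46 and 36 with quantile normalization, 16 and 24 with median centring and 26 and 24 with cyclic loess. For the difference between times, each fit with a single array left out gave 0. The correlation of effects ran from 0.490 to 0.637 with single arrays left out. Blocked fits without replicate 1, 2 or 3 called 112, 0 and 0 at 3 h, 291, 127 and 100 at 6 h, 18, 0 and 0 for the difference, and 660, 581 and 497 in untreated culture. Of 8 lists called at 3 h, 9 at 6 h, 8 for the difference and 1 in untreated culture, the estimated correlation left 5, 7, 3 and 0, and with the block across times besides, 0, 8, 0 and 0, where chemokines and cytokines at 6 h passed (0.0253). In untreated culture the block across times and leaving out the 40% dimmest genes gave 2 each. Lists called with single arrays left out numbered 7 to 13, 7 to 13, 6 to 10 and 0 to 5. The direction of 2 lists turned at 3 h: constitutive proteasome subunits passed (adjusted p = 0.00454) without the interferon alpha array of replicate 3, and Kupffer cell and macrophage markers (0.0117) without that of replicate 1, in the opposite direction to the fit of all arrays. In that fit's own direction they passed without the control 3 h array of replicate 3 (0.00941) and of replicate 1 (0.0257) respectively, and with other arrays left out both ran from 0.114 to 0.999. Over all alternatives the other list results kept their side of the threshold in 2130 cases, gained a call in 49 and lost it in 57. Those of named genes did so in 3733, 34 and 195, with 0 turned, and 6 values without a call moved by more than the spread between replicates. Beyond the results given with blocked values, the block across times with the preset correlation changed no other call of a list or named gene. One probe set per gene leaves out unnamed ones, fewer arrays leave fewer residual degrees of freedom, and a stricter threshold lowers a count by construction. For the other shifts the cause was not tested. Signal over background was examined through the filters on dim probe sets, which gave 128 and 130 calls at 6 h.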

Other observations

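The tests of probe sets that are not the brightest of their gene, and that pattern itself, were chosen after the values were seen, whereas the tests of clock genes and spike-in controls were written down before their results. Apart from the clock genes, which were fixed beforehand with Cirbp and Usp2 left out because their values had been seen, the genes named in this part were chosen after their values were seen, most of them from the fit with the replicate number as a block.

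Several responders at 6 h had large changes that passed with the replicate block alone. The guanylate-binding proteins Gbp7 at 3.60 log2 (adjusted p = 0.129, blocked 0.000774), Gbp2 at 3.43 (0.660, blocked 0.000281) and Gbp4 at 2.84 (1.00, blocked 0.00149) were of this kind. So were the death effector genes Daxx at 1.29 (0.736, blocked 0.000468) and Casp8 at 1.01 (0.134, blocked 0.00330), the caspase inhibitor Xiap at 0.95 (0.139, blocked 0.0241) and Il15, a cytokine of NK and memory T cells, at 0.92 (0.298, blocked 0.0239). At 3 h the poly(A) polymerase family gene Tent5a was at 1.71 log2 (1.00, blocked 0.0375).

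Further single genes passed in untreated culture with the block alone, while the list of hepatocyte transcription factors and differentiated functions did not pass (2 of its 36 genes rose and 3 fell with the block, camera adjusted p = 0.631, 0.693 with the block). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -2.06 log2 (adjusted p = 0.802, blocked 0.0156), with a control SD of 2.03 at 3 h and 3.24 at 6 h. The uptake transporter Slco1b2 was at -0.66 (0.0582, blocked 0.00151) and the transcription factor Onecut1 at -0.75 (0.452, blocked 0.0290), while the bile canalicular exporter Abcc2 was 0.65 higher (0.324, blocked 0.00155) and the transcription factor Foxa2 0.81 (0.261, blocked 0.0120). The chemokine Cxcl12 was at -1.15 (0.479, blocked 0.00164), the chaperone Hspa4 at -0.95 (0.279, blocked 0.000776), and the immediate early gene Ier2 at 0.82 (0.227, blocked 0.00120).

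The changes in untreated culture, 59 probe sets without and 2529 with the block, were set against the clock and against hybridization. A shift in hybridization between the 3 h and 6 h arrays stays open: the 18 hybridization spike-in probe sets were higher at 6 h by 0.1124 log2 in the control arrays and 0.195 in the interferon alpha arrays, and although the arrays of the 2 times overlapped in both, which had been set beforehand as evidence against it, 3 arrays against 3 overlap in all but 10% of cases without any difference and can do so with one. A difference in clock phase between the harvests may contribute but stays open: 16 core clock genes had a median absolute change of 0.25 log2, at percentile 98.19 of 10000 random lists of like level (their median 0.14, their 95th percentile 0.22). The random lists were matched on mean level alone, not on spread between arrays or shared regulation. A percentile over genes therefore cannot decide it. Hlf at -0.82 log2 (blocked adjusted p = 0.00350) and Tef at -0.36 (0.0127), both clock-driven transcription factors, fell with the block, and 0 clock genes passed without it. Sampling time of day is not given in the sources used here, and adaptation to culture was not tested and stays open.

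Some genes rose in untreated culture on a probe set that is not their brightest, such as Cct6a, a chaperonin subunit, at 2.45 log2 (adjusted p = 6.93e-05) against -0.13 on its brightest, and Cirbp, a cold-inducible RNA-binding protein, at 1.17 (adjusted p = 0.136, blocked 0.000222) against 0.12. A further Cirbp probe set that is not its brightest was at 1.27 log2 (adjusted p = 0.249, blocked 0.00022). The pattern was first written as rises of dim probe sets and was redefined once the risen ones proved no dimmer than the fallen ones in the blocked fit (median level 7.57 and 7.56), although the 28 that rose without the block were dimmer than the 31 that fell (6.37 and 7.46). A difference between the arrays that depends on signal level stays open, since the ratio of -0.01903 between the median change of all probe sets in that level range and that of the risen ones is held near 0 by the normalization. Whether the whole transcript pool of these genes rose is also open: over 289 such probe sets the brightest one changed by a ratio of 0.4843, between the bounds of 0.2 and 0.5 set for it, and was called the same way in 94. For 298 fallen ones the ratio was 0.505, with 104 called, so choosing a probe set for its own change may alone give a smaller change on the other one.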
